A study of Mus musculus with 6 samples.

How the data were processed

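The series holds bulk RNA sequencing of 6 HCT116 libraries, 3 from parental cells and 3 from oxaliplatin-resistant cells. Groups and replicate numbers were taken from the sample titles, and table columns were assigned to samples through the sample descriptions. Libraries were made from total RNA with a SMARTER mRNA-Seq kit, per the labels' protocols. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. The labels give the organism as mouse, and the submitters' processing notes name the builds GRCm38 and mm10. The deposited tables, however, carry human Ensembl identifiers and human gene symbols on 30616 of 31456 rows. The identifiers were used as the tables give them, the mouse reference was not used, and no coordinates are reported.

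Read counts per gene were deposited by the authors as whole numbers with no normalization, and the totals were 20246878 to 32138423 per library. A second deposited table holds normalized expression, taken here as FPKM (fragments scaled to gene length and library size) computed by the authors. That unit is an inference from the values, since the header names none. Within a gene the values broadly follow CPM with a factor that differs between genes, and the columns do not sum to a fixed total. For AKR1C1 the factor also differed between libraries. Parental replicate 2 had 1.20 CPM and 0.46 FPKM, and parental replicate 3 had 2.09 CPM and 2.23 FPKM. The 465 rows with no count in any library all had FPKM above 0 in some library, so the FPKM were not computed from the deposited counts alone. They served in alternatives only. Another 840 rows are gene models without an identifier or symbol. Of these 503 were tested, and none is named. Of the rows with a mean of 10 counts or more, 22 had the same counts as another row in every library.

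The main test was edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM normalization, filterByExpr and the robust quasi-likelihood fit (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 16605 genes. Counts of genes are given at the threshold and at the threshold with an absolute log2 fold change of at least 1. The CPM printed are TMM-normalised, with the SD over 3 libraries. The fold changes are fitted ones except for ZNF229 and HYDIN, for which the ratio of summed counts is given with an exact conditional binomial 95% interval. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. With 3 against 3 libraries an exact permutation test of a single gene cannot give a p below 0.10, so no such test was made.

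The 24 gene lists, with 586 distinct symbols, were tested with limma 3.58.1 (camera on voom values, preset inter-gene correlation of 0.01, adjusted over the lists), also with the correlation estimated from the data and with fry. A symbol on several rows was represented by the row with the highest total count, and 27 list symbols had no row of that name and were not analysed. Counts of members use the edgeR adjusted p over all tested genes, and also adjusted over the list alone.

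The gene lists, the rule for the genes named and the first set of alternatives were chosen before the data were examined. The rule took the AKR1C and AKR1B genes and STAT3. It also took the 10 largest rises and 10 largest falls with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 5 CPM, no overlap between the groups and no clone name. From each list it took up to 4 members with the smallest adjusted p, and a member of several lists is named under one of them. Some genes under this rule are not described in the text. The genes CCNE1, CDK1, RRM1, CDT1, AKR1A1, PMVK and CDH1 fall outside this rule and were named after their values were seen. This also applies to SLC31A1, SLC31A2, ATP7A, ATP7B, CDKN1A, MDM2, FAS, TP53I3, RRM2B and CCNG1. The same holds for genes that appear only in the closing section, with exceptions. COL1A2, COL3A1, DCN, LUM and the LXR targets were set for their tests before the results were seen.

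The edgeR and set tests were tested on simulated data with the real libraries' means and sizes. With 50 genes changed by each fold in 16400 genes fitted, edgeR recovered 31 at 1.25-fold, 48 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, with 8 false calls. Of 40 unchanged lists camera and fry called 0, and of 5 raised lists they called 5. The changed genes were drawn from those with an expected count over 50, and all genes and libraries were given the same dispersion. The recovery and false calls therefore do not apply to genes with fewer counts or a wider spread between libraries. The simulated genes were drawn independently and few of them changed, whereas 53.8% of tested genes passed the threshold in the real data. The simulation therefore does not show how often lists of correlated genes are called falsely.

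The alternatives of this first set were RLE size factors, library sizes alone, DESeq2 1.42.0, no filter on low counts, at least 1 CPM in at least 3 libraries, a replicate block, limma on log2(FPKM + 1) with a mean FPKM of at least 1, the same with a pseudocount of 0.1 or with no filter, each library left out in turn, and a glmTreat test against a 2-fold change. For the lists they were the estimated correlation, fry, RLE, the 1 CPM filter, the block and each library left out. Alternatives added later were removal of a trend on implied transcript length (CPM divided by FPKM, which 100% of tested genes had), leaving out the mitochondrially encoded genes, leaving out the rows without a gene name, summing AKR1C1, AKR1C2 and AKR1C3, and leaving SCD out of a family of fatty acid synthesis genes.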

Results

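RNA sequencing was carried out on HCT116, an established human colorectal carcinoma cell line, in a parental form and in an oxaliplatin-resistant form. Oxaliplatin is a platinum drug that forms DNA adducts and is used against colorectal cancer. Each group held 3 libraries, numbered 1 to 3. The total count was 27303582, 32138423 and 20246878 in parental replicates 1, 2 and 3, and 24039045, 28432096 and 25136365 in resistant replicates 1, 2 and 3. At these depths 3 counts, taken as the floor of detection in a library, corresponded to between 0.0933 and 0.148 CPM, the usual unit of read counts scaled to library size. Floors and intervals cover counting error only. The labels did not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries.

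The libraries separated by group on the first principal component, which held 71.1% of the variance of log2 CPM. The second component held 10.8% and set parental replicate 2, at -31.5, apart from parental replicates 1 and 3, at 9.99 and 22.5. The correlation of log2 CPM across genes was 0.988 to 0.992 within the parental group, 0.992 within the resistant group and 0.962 to 0.966 between the groups. No pair of replicates agreed within sampling noise. The chi-square per gene, near 1 for sampling noise alone, was 12.6 and 12.2 for the pairs with parental replicate 2, 2.06 for parental replicates 1 and 3, and 2.80 to 4.83 in the resistant group. The mitochondrially encoded mRNAs took 4.79% to 5.07% of the counts in the parental libraries and 6.33% to 6.95% in the resistant libraries.

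The comparison addressed which genes differ between the resistant and the parental form of the line, with AKR1C1 and STAT3 named in the title of the study. The labels did not say how the resistant cells were derived. A difference between the forms therefore cannot be assigned to resistance itself. AKR1C1 (ENSG00000187134.14), an aldo-keto reductase that reduces steroids and other carbonyl compounds, was 2.48-fold higher in the resistant cells. Its level was 1.95 ± 0.687 CPM in the parental and 4.76 ± 0.414 CPM in the resistant libraries (SD, n = 3), which rested on 68, 37 and 41 counts and on 111, 153 and 119 counts. The log2 fold change was 1.31 ± 0.22 (SE) with an adjusted p of 5.6e-04 in edgeR's quasi-likelihood test, and each resistant library lay above each parental library. STAT3 (ENSG00000168610.14), the transcription factor of the interleukin 6 pathway, had 89.7 ± 1.89 CPM in the parental and 92.4 ± 2.10 CPM in the resistant libraries (SD, n = 3). The STAT3 log2 fold change was 0.04 ± 0.04 (SE), edgeR adjusted p = 0.44. STAT3 passed the threshold with library sizes alone (log2 fold change 0.14, edgeR adjusted p = 0.020) and had a log2 fold change of -0.0095 with a trend on transcript length removed, and its adjusted p ranged from 0.020 to 0.88 over all alternatives. These values describe STAT3 mRNA, and its phosphorylation was not measured.

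Of the paralogs of AKR1C1, AKR1C3 (ENSG00000196139.14) was 6.31-fold higher in the resistant cells, at 6.61 ± 0.152 CPM against 1.08 ± 0.776 CPM (SD, n = 3; log2 fold change 2.66 ± 0.49 SE, edgeR adjusted p = 0.0053). The AKR1C3 log2 fold change was 3.36 without parental replicate 1 and 2.11 without parental replicate 2. AKR1C2 (ENSG00000151632.17) had 1.87 ± 1.39 CPM in the parental and 2.97 ± 0.303 CPM in the resistant libraries (log2 fold change 0.73 ± 0.73 SE, edgeR adjusted p = 0.45). The AKR1C2 log2 fold change was 0.16 without parental replicate 2, and 1.12 and 1.09 without parental replicates 1 and 3, none of them past the threshold. AKR1B10 (ENSG00000198074.10) rose 3.93-fold, from 2.68 ± 1.35 CPM to 10.3 ± 0.490 CPM (edgeR adjusted p = 0.0052). AKR1B1 (ENSG00000085662.14), the aldose reductase gene, rose 2.0-fold, from 43.3 ± 2.10 CPM to 86.6 ± 1.08 CPM (edgeR adjusted p = 1.8e-08). AKR1B15 had between 2 and 11 counts per library, too few for the test, and AKR1C4 was not analysed here. Parental replicate 2 had the lowest CPM of AKR1C1, AKR1C2, AKR1C3 and AKR1B10, with 8 counts of AKR1C2 and 8 of AKR1C3. The transcripts of AKR1C1, AKR1C2 and AKR1C3 are near-identical over long stretches, as are those of AKR1B10 and AKR1B15, so the division of reads within each group of paralogs is uncertain. On the FPKM values the AKR1C1 call depended on the pseudocount and the filter, with limma adjusted p-values of 0.046, 0.083 and 0.093 against a range of 8.4e-13 to 0.093 over all alternatives.

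**Figure D1:**
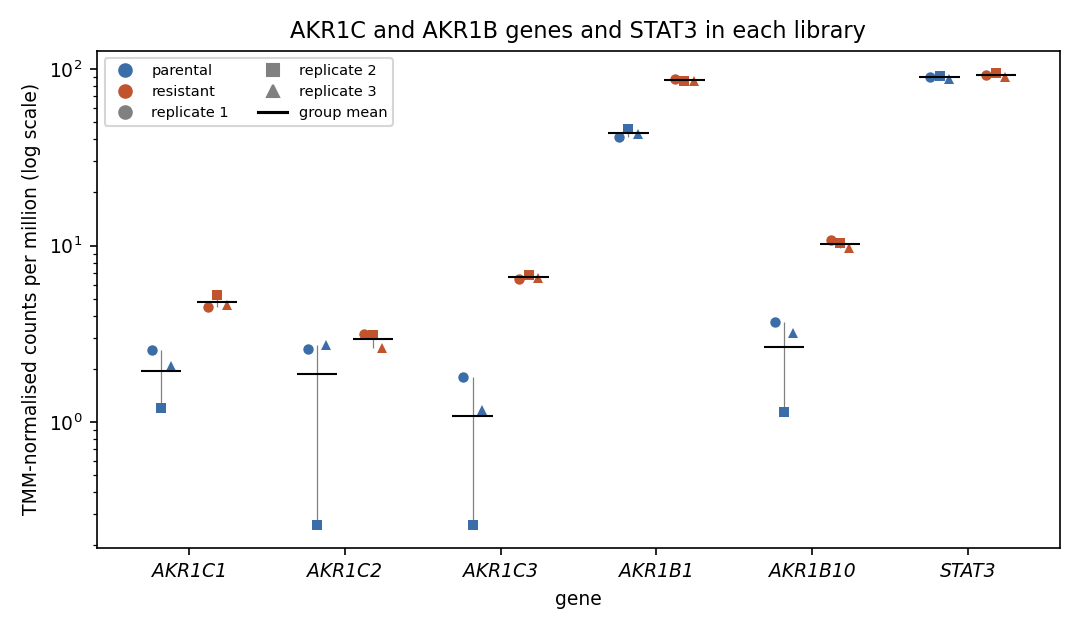
Normalised read counts in CPM, on a log scale, of 5 aldo-keto reductase genes and STAT3 in each of the 6 libraries. Symbols mark the replicate, black lines the group means and grey lines the range of the 3 libraries of a group; the AKR1C1 mean was 1.95 CPM in parental and 4.76 CPM in resistant libraries, and the STAT3 means were 89.7 and 92.4 CPM.

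Across the genome 8933 of 16605 tested genes (53.8%) passed the threshold of an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these genes past the threshold 4534 were higher and 4399 lower in the resistant cells. Among them 5866 changed by less than 1.5-fold, and 1353 changed at least 2-fold, 926 higher and 427 lower. With library sizes alone in place of normalization factors, the median log2 fold change of all tested genes shifted from 0.02 to 0.11, and 5933 of 9079 called genes (65.4%) were higher, against 50.8% in the TMM fit. Of the genes past the threshold with at least a 2-fold change 638 also passed when the test itself was made against a 2-fold change.

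Among genes with a symbol, a mean of 5 CPM or more and no overlap between the groups, the largest fitted rise was that of ZNF229, a zinc finger gene. It had 1 count over the parental libraries together, in replicate 2, and 856 over the resistant libraries. Without parental replicate 2 it had no parental count. Its ratio was 823 with a 95% counting interval of 147 to 32550, and its resistant level was 10.7 ± 1.18 CPM (SD, n = 3). VIM, which encodes the intermediate filament protein vimentin, rose 52.4-fold from 17.5 ± 1.08 CPM to 916 ± 3.06 CPM. DHRS2, a short-chain dehydrogenase/reductase gene, rose 33.7-fold from 28.7 ± 3.37 CPM to 972 ± 32.5 CPM. TTN, the gene of the muscle protein titin, rose 45.5-fold from 5.0 ± 0.522 CPM to 229 ± 27.5 CPM. EHF, an epithelial ETS transcription factor, rose 42.4-fold, from 1.33 ± 0.380 CPM to 54.8 ± 0.667 CPM. The protease-activated receptor gene F2RL2 rose 46.6-fold and the aldehyde dehydrogenase gene ALDH3A1 28.3-fold. The remaining genes of this group were ZNF702P (32.4-fold), C1QTNF12 (24.1-fold) and the long non-coding RNA PURPL (22.2-fold). The edgeR adjusted p-values of these 10 genes were 6.2e-09 (ZNF702P) or lower.

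The 10 largest falls at this level included 3 interferon-induced genes and 3 genes of lipid synthesis or its regulation. IFIT2 fell from 59.7 ± 2.85 CPM to 4.54 ± 0.316 CPM (13.2-fold), IFIT3 fell 12.2-fold and OASL 11.5-fold. SCD, the stearoyl-CoA desaturase gene, fell 11.5-fold from 2958 ± 18.6 CPM to 258 ± 6.32 CPM. SQLE, the squalene epoxidase gene, fell 10.4-fold, and INSIG1, a regulator of sterol synthesis, fell 11.1-fold. ID2, an inhibitor of basic helix-loop-helix transcription factors, fell 16.0-fold from 57.0 ± 0.717 CPM to 3.57 ± 0.712 CPM. The teneurin gene TENM3 fell 23.8-fold, the lipase gene LIPG 19.7-fold and the phosphodiesterase gene PDE4B 11-fold. The edgeR adjusted p-values of the 10 genes were 1.9e-08 (TENM3) or lower.

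**Figure D2:**
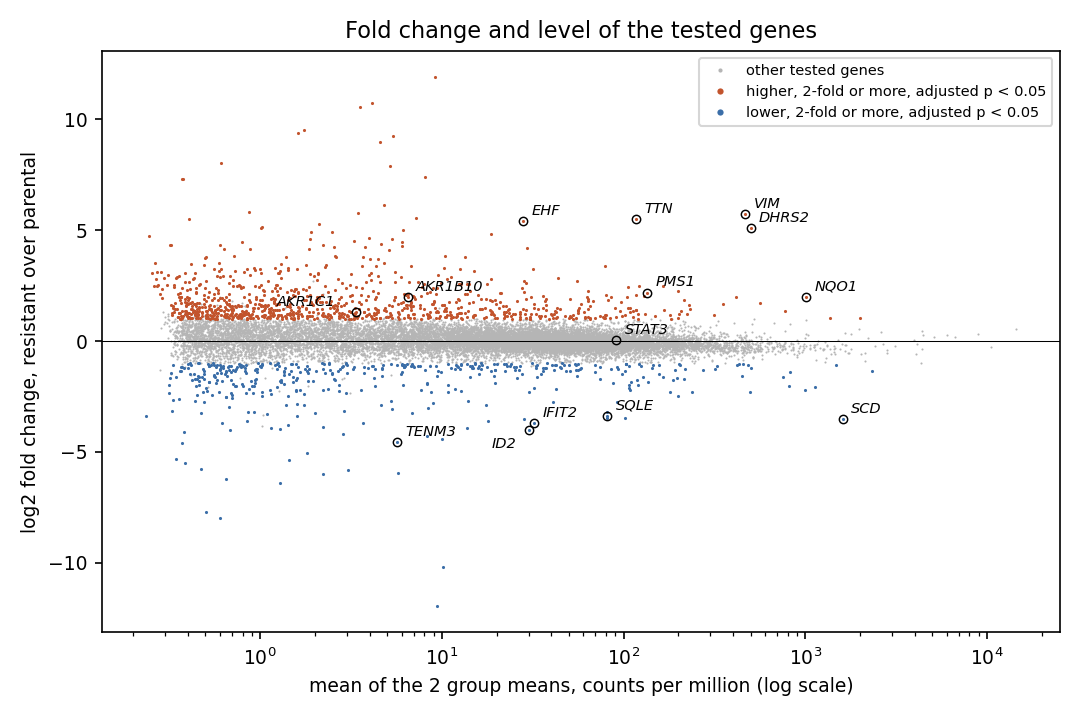
Fitted log2 fold change of resistant over parental libraries (vertical axis) against the mean of the group means in CPM (horizontal axis, log scale) for the 16605 tested genes, with 14 genes named. Of the coloured genes, which changed at least 2-fold with an adjusted p under 0.05, 926 lay above and 427 below the zero line; fitted fold changes of genes with few or no counts in one group depend on the prior count.

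Of 24 gene lists 14 passed the threshold in camera with a preset correlation, 10 of them higher and 4 lower in the resistant cells. With an estimated correlation 1 list kept its call, the cholesterol synthesis list. In fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, 22 lists passed.

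Genes of cholesterol synthesis and uptake fell together. Of 25 measured members 24 fell and none rose, with PMVK not past the threshold, and 25 fell adjusted over the list alone. The median log2 fold change was -1.69, a 3.22-fold lower level. HMGCS1, the HMG-CoA synthase gene, fell 4.88-fold from 300 ± 12.0 CPM to 61.6 ± 2.79 CPM. FDFT1, the squalene synthase gene, fell 5.64-fold. The camera adjusted p was 2.2e-19, and adjusted p = 0.021 with an estimated correlation.

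Genes of the interferon response also fell. Of 31 measured members 24 fell, 5 rose and 2 did not pass the threshold, and 25 fell adjusted over the list alone. The median log2 fold change was -0.88. IFIT1, an interferon-induced RNA-binding protein gene, fell 6.75-fold from 70.7 ± 0.602 CPM to 10.5 ± 0.0633 CPM, beside IFIT2, IFIT3 and OASL above. In camera the adjusted p was 3.9e-08, and adjusted p = 0.074 with an estimated correlation.

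Cell cycle genes were mostly lower. Of 35 measured members 24 fell, 4 rose and 7 did not pass the threshold, with the same counts adjusted over the list alone and a median log2 fold change of -0.38. The mitotic genes CCNB1, PLK1 and KIF20A fell 2.10-fold, 2.17-fold and 2.19-fold, and the spindle checkpoint kinase gene BUB1 fell 1.59-fold. The 4 members that rose were CCNE1, CDK1, RRM1 and CDT1, by 0.15 to 0.29 on the log2 scale. The list had a camera adjusted p of 5.4e-06, and adjusted p = 0.099 with an estimated correlation.

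Targets of NRF2, the transcription factor of the oxidative stress response, rose. Of 24 measured members 20 rose, 1 fell and 3 did not pass the threshold. Adjusted over the list alone, 20 rose and 2 fell. The list held no aldo-keto reductase, and its median log2 fold change was 0.86. NQO1, a quinone reductase gene, rose 3.94-fold from 409 ± 5.15 CPM to 1612 ± 11.8 CPM. OSGIN1 rose 10.6-fold, SRXN1, the sulfiredoxin gene, 3.13-fold, and TRIM16L 5.21-fold, the last uncertain because TRIM16L is a close copy of TRIM16. By camera the adjusted p was 1.3e-08, and adjusted p = 0.074 with an estimated correlation. Of the list's 26 members 6 were also in other lists, among them GCLC, GCLM and ABCC2.

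In the glutathione metabolism list 8 of 21 measured members rose, 2 fell and 11 did not pass the threshold, the same adjusted over the list alone. GSR, the glutathione reductase gene, rose 2.24-fold. GCLC and GCLM, the subunits of the enzyme that limits glutathione synthesis, rose 2.09-fold and 2.53-fold. GSTM2 rose 2.04-fold, which is uncertain because GSTM genes are close copies. The camera adjusted p of 0.0499 lay at the threshold, and adjusted p = 0.21 with an estimated correlation. Without parental replicate 1, resistant replicate 1 or resistant replicate 2 the camera adjusted p was 0.064, 0.095 or 0.052. With RLE size factors it was 0.052, and with at least 1 CPM in 3 libraries it was 0.057.

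Aldo-keto reductases, a list drawn from the study's title and therefore not independent evidence of a direction, had 4 of 10 measured members higher, 1 lower and 5 not past the threshold, the same adjusted over the list alone. AKR1C1, AKR1C3, AKR1B1 and AKR1B10 were the 4 that rose and AKR1A1 fell. Tested with camera, the adjusted p was 0.14, and adjusted p = 0.28 with an estimated correlation.

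The list of STAT3 pathway members and targets, also drawn from the study's title, had 7 of 25 measured members higher, 7 lower and 11 not past the threshold, the same adjusted over the list alone. MYC fell 1.86-fold from 320 ± 3.19 CPM to 172 ± 2.33 CPM, and BIRC5, the survivin gene, fell 1.32-fold. HIF1A rose 1.35-fold and IL6ST, the gp130 receptor subunit gene, rose 1.47-fold. The median of the list was 0.02 and its mean -0.03 on the log2 scale. The camera adjusted p was 0.97 in the higher direction, and adjusted p = 0.98 with an estimated correlation.

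Genes of platinum transport and copper handling were higher as a list, with 9 of 14 measured members higher, 2 lower and 3 not past the threshold, the same adjusted over the list alone. ABCG2, a multidrug efflux pump gene, rose 3.43-fold from 4.14 ± 0.554 CPM to 14.1 ± 0.686 CPM. ABCC3 rose 1.98-fold and the copper chaperone gene ATOX1 1.85-fold. ABCC2, an efflux pump gene, fell 2.37-fold from 130 ± 7.24 CPM to 54.9 ± 0.639 CPM. The copper transporter genes went both ways. The log2 fold change was 0.20 for SLC31A1, 0.42 for ATP7A and -0.81 for SLC31A2, and ATP7B did not pass the threshold. The list median was 0.32 on the log2 scale. Uptake and efflux genes are mixed in the list, so its direction does not give a direction of platinum transport. In camera the adjusted p was 0.032, and adjusted p = 0.15 with an estimated correlation. With at least 1 CPM in 3 libraries the camera adjusted p was 0.081.

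Among aldehyde dehydrogenases and other drug-metabolising enzymes 11 of 23 measured members rose, 4 fell and 8 did not pass the threshold, the same adjusted over the list alone. Beside ALDH3A1, the fatty aldehyde dehydrogenase gene ALDH3A2 rose 2.71-fold from 125 ± 3.59 CPM to 339 ± 9.78 CPM and CYP4F11 rose 3.93-fold, the last uncertain because CYP4F genes are close copies. CYP24A1, the vitamin D hydroxylase gene, fell 3.58-fold. The list had a camera adjusted p of 0.012, and adjusted p = 0.099 with an estimated correlation. In the metallothionein list MT1X and MT2A rose 2.27-fold and 1.35-fold among 4 measured members, and none fell. Adjusted over the list alone, 2 rose and 1 fell. By camera the adjusted p was 0.41, adjusted p = 0.68 with an estimated correlation, and metallothionein genes are close copies of each other.

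DNA repair lists did not pass the threshold. In nucleotide excision repair 4 of 29 measured members rose, 7 fell and 18 did not pass, and 4 rose and 6 fell adjusted over the list alone. ERCC1, a subunit of the nuclease that excises platinum adducts, rose 1.47-fold from 61.2 ± 3.41 CPM to 90.4 ± 4.93 CPM. LIG3 and DDB1 fell 1.39-fold and 1.29-fold. Tested with camera, the adjusted p was 0.54, and adjusted p = 0.59 with an estimated correlation. In the Fanconi anaemia and homologous recombination list 10 of 29 measured members rose, 8 fell and 11 did not pass, and 12 rose and 8 fell adjusted over the list alone. The helicase gene BLM rose 1.47-fold and FANCL 1.46-fold, and FANCE and RAD50 fell 1.38-fold and 1.24-fold. The camera adjusted p was 0.57, and adjusted p = 0.65 with an estimated correlation. In the mismatch repair and translesion synthesis list 3 of 16 measured members rose, 1 fell and 12 did not pass, the same adjusted over the list alone. PMS1, a MutL homolog, rose 4.53-fold from 48.9 ± 4.09 CPM to 222 ± 11 CPM (edgeR adjusted p = 1.8e-10). EXO1 rose 1.20-fold, POLH 1.12-fold, and RAD18 fell 1.29-fold. The edgeR adjusted p of POLH was 0.016, and 0.076 and 0.066 without parental replicate 1 and 3 and 0.059 without resistant replicate 3, within a range of 9.5e-04 to 0.092 over its alternatives. The RAD18 call was lost on FPKM with no filter (limma adjusted p = 0.11, the upper end of a range from 1.7e-09 to 0.11 over its alternatives). For this list camera gave an adjusted p of 0.46, and adjusted p = 0.65 with an estimated correlation.

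Targets of p53 rose as a list, with 16 of 28 measured members higher, 4 lower and 8 not past the threshold, the same adjusted over the list alone. GDF15, a stress-induced cytokine gene, rose 2.46-fold from 62.4 ± 2.16 CPM to 154 ± 4.31 CPM. SESN2 rose 2.0-fold, the death receptor gene TNFRSF10B 1.61-fold and SFN 1.52-fold. Most changes were smaller, with a list median of 0.26 on the log2 scale. CDKN1A and MDM2 rose by 0.27 and 0.24 on that scale, and the 4 that fell were FAS, TP53I3, RRM2B and CCNG1. In camera the adjusted p was 0.0014, and adjusted p = 0.099 with an estimated correlation. Among apoptosis regulators 10 of 27 measured members rose, 4 fell and 13 did not pass, the same adjusted over the list alone. The genes that rose act on either side of apoptosis. The pro-apoptotic BCL2L11 and APAF1 rose 1.87-fold and 1.99-fold, and BIRC3, an inhibitor of apoptosis, rose 3.12-fold. The list had a camera adjusted p of 0.19, and adjusted p = 0.48 with an estimated correlation.

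The list of ATF4 targets and unfolded protein response genes rose, with 18 of 27 measured members higher, 2 lower and 7 not past the threshold, the same adjusted over the list alone. DDIT3, the CHOP gene, rose 2.51-fold from 15.3 ± 0.867 CPM to 38.6 ± 1.96 CPM. CRELD2 rose 2.28-fold and the asparagine synthetase gene ASNS 1.59-fold, and SESN2, named above, was also a member. By camera the adjusted p was 3.3e-04, and adjusted p = 0.099 with an estimated correlation. NF-kB and inflammatory genes rose, with 13 of 21 measured members higher, 3 lower and 5 not past, the same adjusted over the list alone. ICAM1, an adhesion molecule gene, rose 13-fold from 0.556 ± 0.115 CPM to 7.46 ± 0.378 CPM. RELB rose 2.79-fold and TNFAIP3, a feedback inhibitor of NF-kB, 2.76-fold. Tested with camera, the adjusted p was 0.0042, and adjusted p = 0.099 with an estimated correlation.

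Mesenchymal markers rose as a list, with 14 of 22 measured members higher, 4 lower and 4 not past the threshold, and 15 higher and 4 lower adjusted over the list alone. Beside VIM, CCN2 rose 6.54-fold from 7.50 ± 0.501 CPM to 49.4 ± 1.18 CPM. The fibronectin gene FN1 rose 2.85-fold and LOXL2, a lysyl oxidase gene, 2.71-fold. The camera adjusted p was 3.3e-04, and adjusted p = 0.074 with an estimated correlation. Epithelial markers were lower as a list, with 13 of 24 measured members lower, 5 higher and 6 not past, the same adjusted over the list alone, and a median log2 fold change of -0.16. ST14, the matriptase gene, fell 2.03-fold, the splicing regulator gene ESRP1 1.91-fold and the claudin gene CLDN7 1.47-fold. EHF, above, was among the members that rose, and the E-cadherin gene CDH1 also rose, by 1.17-fold. In camera the adjusted p was 0.015, and adjusted p = 0.48 with an estimated correlation.

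Wnt and intestinal stem cell genes went both ways, with 7 of 16 measured members higher, 7 lower and 2 not past the threshold, the same adjusted over the list alone. AXIN2, a feedback target of Wnt signalling, rose 2.31-fold and TNFRSF19 10.5-fold. CD44 fell 1.77-fold from 736 ± 19.3 CPM to 416 ± 7.14 CPM, and MYC is given above. The median was 0.01 and the mean 0.19 on the log2 scale, while the camera direction was lower, with an adjusted p of 0.79 and adjusted p = 0.79 with an estimated correlation. Of the differentiated intestinal cell markers 5 of 28 were measured, 2 higher, 1 lower and 2 not past the threshold, the same adjusted over the list alone. CEACAM1 fell 3.36-fold, which is uncertain because CEACAM genes are close copies. CA2, a carbonic anhydrase gene, rose by 0.32 on the log2 scale. KRT20 rose 2.18-fold at 0.340 ± 0.0157 CPM and 0.751 ± 0.272 CPM, with an edgeR adjusted p of 0.018 that was 0.0504, 0.0652 and 0.0896 without parental replicate 1, resistant replicate 1 and resistant replicate 3, within a range of 0.0047 to 0.97 over its alternatives. For these markers camera gave an adjusted p of 0.97 in the higher direction against a median of -0.08 and a mean of -0.09, and adjusted p = 0.98 with an estimated correlation.

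The hypoxia and glycolysis list was higher, with 13 of 31 measured members higher, 5 lower and 13 not past the threshold, and 15 higher and 5 lower adjusted over the list alone. The peptide hormone gene ADM rose 2.02-fold, P4HA1 2.21-fold and the histone demethylase gene KDM3A 1.51-fold. The glucose transporter gene SLC2A3 fell 2.36-fold. Across the list the shift was small, with a median log2 fold change of 0.11. The list had a camera adjusted p of 0.043, and adjusted p = 0.56 with an estimated correlation. Without parental replicate 1 or 3 the camera adjusted p was 0.11 or 0.074, without resistant replicate 1 or 2 it was 0.0566 or 0.0501, and with at least 1 CPM in 3 libraries it was 0.057.

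Of the 13 mitochondrially encoded mRNAs 9 rose, none fell and 4 did not pass the threshold, and 10 rose adjusted over the list alone. MT-CO1 rose 1.44-fold from 11836 ± 785 CPM to 17090 ± 836 CPM. MT-CYB rose 1.39-fold and MT-ND1 1.34-fold. MT-ND4L rose 1.31-fold, which is uncertain because it overlaps MT-ND4, and its limma adjusted p on FPKM was 0.26 to 0.42, the upper end of a range from 1.9e-10 to 0.42 over its alternatives. By camera the adjusted p was 0.0038, and adjusted p = 0.28 with an estimated correlation. Of 24 markers of blood, stromal and endothelial cells 7 were measured, 3 higher, 1 lower and 3 not past, the same adjusted over the list alone. COL1A1, a collagen gene, rose 1.71-fold from 24.3 ± 1.79 CPM to 41.7 ± 2.91 CPM, and the lysosomal protein gene CD68 rose 1.30-fold. PDGFRB rose 3.29-fold at 0.162 ± 0.0519 CPM and 0.569 ± 0.120 CPM, and DES fell 2.03-fold. On FPKM the limma adjusted p of DES was 0.11 to 0.23, and that of PDGFRB was 0.49 with no filter. Tested with camera, the adjusted p was 0.26, and adjusted p = 0.53 with an estimated correlation. List medians kept their sign under RLE size factors and under library sizes alone, except that nucleotide excision repair went from -0.03 to 0.07 and the differentiated intestinal markers from -0.08 to 0.02 under library sizes alone, and the Wnt list from 0.01 to -0.01 under RLE.

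**Figure D3:**
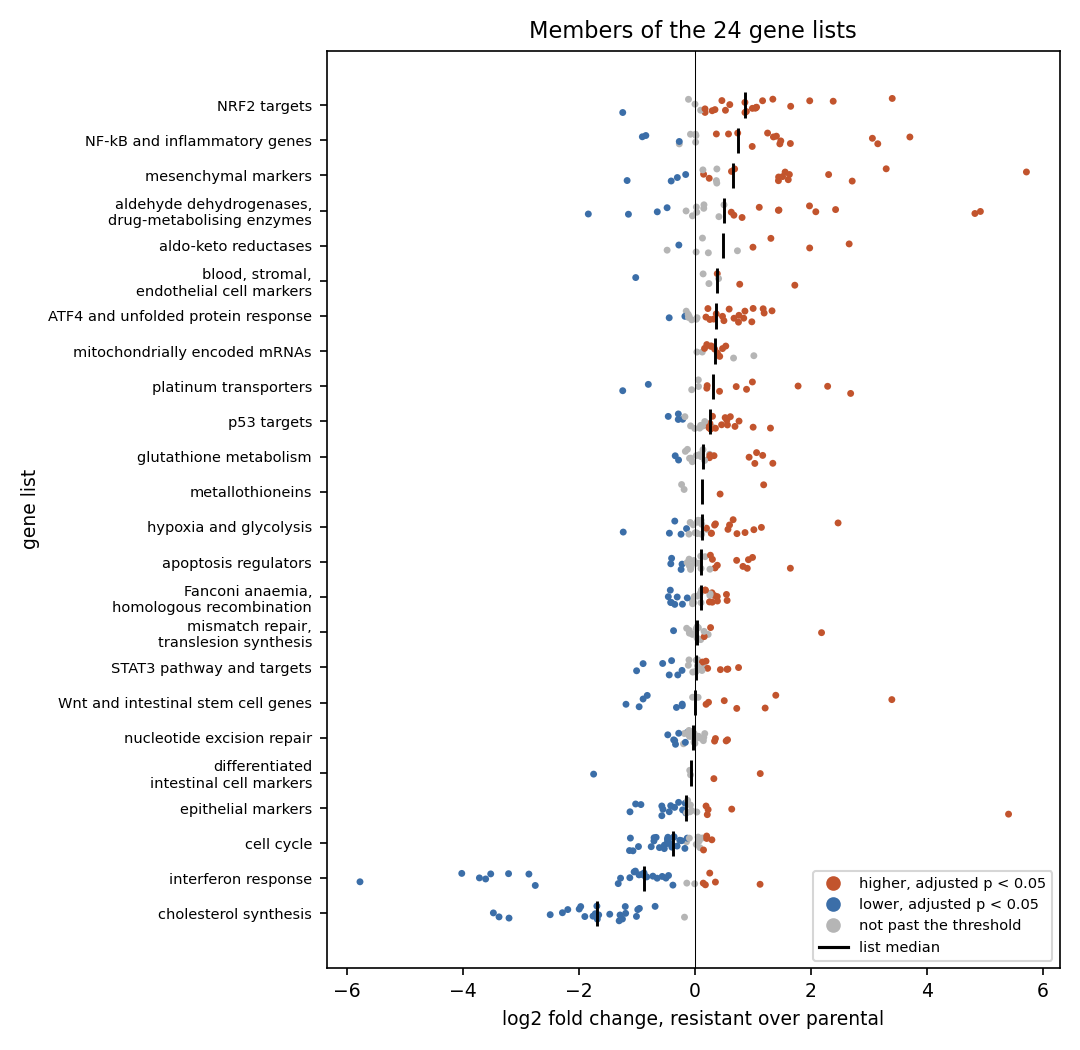
Fitted log2 fold change, resistant over parental, of each measured member of the 24 gene lists, with list medians as black bars and colours for members past an adjusted p of 0.05. The median was -1.69 for cholesterol synthesis, -0.88 for the interferon response and 0.86 for NRF2 targets.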

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

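The removal of the length trend, the fits without mitochondrially encoded genes or unnamed rows, and the AKR1C sum were chosen after the data were seen. Among 104 genes under the naming rule 1834 of 1858 values under 18 alternatives kept direction and side of the threshold, 21 lost the call, 1 gained it and 2 reversed. Genes under the mean of 1 FPKM or 1 CPM, and the left-out mitochondrial genes, gave no value in those fits. Low counts limit the precision for AKR1C2 and AKR1C3, with 8 each in parental replicate 2, the deepest library, and for ZNF229, with 1 over the parental libraries.

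The count of 8933 genes past the threshold lay between 7666 and 9209 when 1 library was left out and was 7591 in DESeq2. It was 5290 on FPKM with no filter, with 4844 genes shared with the main count. The count of 1353 genes past the threshold with at least a 2-fold change was 552, 842 and 581 on FPKM with a pseudocount of 1, a pseudocount of 0.1 and no filter, and 638 in the test against a 2-fold change, which is stricter by construction. Under the same filter, lowering the pseudocount from 1 to 0.1 raised the 2-fold count from 552 to 842, so part of that drop follows from the pseudocount. The cause was not tested for the other FPKM differences.

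AKR1C1 kept its direction in 18 of 18 alternatives. Its log2 fold change was 1.53 (limma adjusted p = 0.083) with the FPKM pseudocount of 0.1 and 1.04 (0.093) with no FPKM filter, both no longer past the threshold, and 1.02 to 1.57 with 1 library left out. STAT3 passed with library sizes alone (log2 fold change 0.14, edgeR adjusted p = 0.020), which follows from the shift of all genes, and was -0.0095 with the length trend removed. KRT20 was -0.0265 on FPKM with no filter. The cause was not tested for AKR1C1, STAT3 with the length trend removed, or KRT20.

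With the estimated correlation the camera adjusted p was 0.074 for NRF2 targets, mesenchymal markers and the interferon response, and 0.099 for p53 targets, cell cycle, NF-kB, ATF4 and drug-metabolising enzymes. It was 0.15 for platinum transporters, 0.21 for glutathione metabolism, 0.28 for mitochondrially encoded mRNAs, 0.48 for epithelial markers and 0.56 for hypoxia. With at least 1 CPM in 3 libraries it was 0.081 for platinum transporters and 0.057 for both glutathione metabolism and hypoxia, and RLE gave 0.052 for glutathione. Leaving out 1 library gave 0.019 to 0.095 for glutathione and 0.0037 to 0.11 for hypoxia. In fry, which asks another question, 8 lists gained a call: aldo-keto reductases (2.9e-04), metallothioneins (0.027), nucleotide excision repair (0.043), Fanconi and homologous recombination (0.035), mismatch repair and translesion synthesis (0.011), apoptosis regulators (0.0050), Wnt (6.1e-04) and the blood, stromal and endothelial markers (0.012). Lists not past the threshold turned direction in 8 values. For STAT3 these were fry (0.18), RLE (0.98) and leaving out parental replicate 3 or resistant replicate 1 or 3, with 0.945 to 0.997 over the libraries left out. For the differentiated intestinal markers they were fry (0.57), the 1 CPM filter (0.81) and leaving out parental replicate 1, with 0.918 to 0.997 over the libraries left out. The cause was not tested. The cholesterol synthesis list kept its call in 11 of 11 alternatives, with adjusted p-values of 2.2e-21 to 0.021.

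The labels gave same-numbered parental and resistant libraries no link beyond the number. Their deviations correlated at 0.07, 0.14 and 0.01 across genes for replicates 1, 2 and 3. Parental replicates 1 and 2 correlated best with the resistant library of the same number, and parental replicate 3 with resistant replicate 1 (0.09). Whether the libraries were paired therefore stays open. With the replicate block there were 9973 genes past the threshold, 8851 of them shared with the count without it, and 1362 genes past the threshold with at least a 2-fold change. AKR1C1 had a log2 fold change of 1.33 and STAT3 0.04 under the block. AKR1C3 had 2.73 with an edgeR adjusted p of 0.055, and no other gene under the rule and no list changed its call.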

Other observations

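The gene families of the next paragraph, the AKR1C, NRF2, epithelial and coefficient-of-variation tests, and the genes listed in the last paragraph were chosen after results were seen. The splits of the libraries, the length trend, the stromal share and the LXR test were set before their results were seen.

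The fall of lipid synthesis genes extended to fatty acids. Of 12 measured fatty acid synthesis genes 10 fell, none rose and 2 did not pass the threshold, with a median log2 fold change of -1.05. The family was chosen after results were seen, among them the falls of SCD, one of its members, and of the cholesterol synthesis genes. Leaving SCD out does not undo that choice, so the camera p-values of this family are no independent evidence. Without SCD 9 of 11 fell, with a median of -0.99, a camera adjusted p of 1.1e-06 and adjusted p = 0.037 with an estimated correlation. FASN, the fatty acid synthase gene, fell 4.21-fold from 1822 to 433 CPM, ACACA 2.45-fold, and SREBF1, which encodes the regulator SREBP1, 2.81-fold. With SCD the camera adjusted p over the 7 families was 5.7e-08, and adjusted p = 0.026 with an estimated correlation. The other 6 families did not pass in camera. Of 6 measured EGF receptor ligand genes 4 fell and 2 rose (camera adjusted p = 0.41, adjusted p = 0.85 with an estimated correlation). EREG fell 4.96-fold from 822 to 166 CPM, and EGF rose 4.86-fold from 0.895 to 4.29 CPM. AREG fell 6.80-fold, uncertain because of a near-identical copy in the annotation. ERK feedback genes had 8 of 14 higher and 3 lower (0.41, and 0.85), with DUSP6 rising 1.54-fold. ID and BMP response genes had 3 of 8 measured higher and 2 lower (0.79, and 0.85). ID3 fell with ID2, by 1.19 on the log2 scale, while BMP4 rose 2.61-fold. YAP targets (6 of 13 higher, 4 lower) and HLA class I and antigen presentation genes (2 of 13 higher, 4 lower) had 0.79 and 0.85.

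Resistant and parental libraries differed in 8933 genes, 1353 of them at least 2-fold. The 3 against 3 libraries give 10 splits, so a share under 0.05 cannot be reached; 1 of the 10, the real one, gave as many genes at each limit. The highest of the other 9 splits gave 0 genes in edgeR, with 63 to 357 at an unadjusted p under 0.05 and 0 to 7 in DESeq2. Each of these 9 splits set libraries of both groups on each side. The group difference then widened the spread within a side, so a low count of genes followed from the design of the splits. For gene lists 1 split, the real one, gave as many as its 14. The other 9 splits gave 3 to 8 lists in camera, although none of them gave a gene in edgeR. With a length trend removed from each library 9026 genes passed, 8520 of them shared, which argues against a length trend as the cause of the count. The biological coefficient of variation was 0.0577, and the labels name no separate cultures. Whether the replicates share a culture or a preparation, which might make small differences pass the threshold, therefore stays open.

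The higher AKR1C level in resistant libraries was weighed against reads shared between paralogs, 1 low library and a wider response. Summed over AKR1C1, AKR1C2 and AKR1C3 the count was 3.01-fold higher (log2 fold change 1.59 ± 0.49 SE, edgeR adjusted p = 0.048), which argues against reads exchanged among these 3 genes as the whole cause. The sum cannot show which of the 3 genes rose, so for AKR1C1 alone an exchange of reads with AKR1C3 stays open. Without parental replicate 2, the lowest library, it was 2.20-fold higher (adjusted p = 6.6e-08), which argues against that library as the whole cause. With AKR1C1, AKR1C2 and AKR1C3 summed the call was lost without parental replicate 3 (adjusted p = 0.099) and without resistant replicate 1, 2 or 3 (0.12, 0.12 and 0.12), at log2 fold changes of 1.55 to 1.75. The NRF2 list rose in camera (adjusted p = 1.3e-08, adjusted p = 0.074 with an estimated correlation), so the AKR1C rise may be part of a wider rise of NRF2 targets, a hypothesis found and tested on the same data.

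VIM rose 52.4-fold in the resistant libraries. If stromal cells had brought it, their collagens and proteoglycans would be there too, but COL1A2, COL3A1, DCN and LUM, with 25 counts of COL3A1 and 2 or fewer of each of the others over the resistant libraries, together reached at most 0.0446% of the VIM level in a resistant library. COL1A1 (24.3 to 41.7 CPM), SPARC (0.259 to 2.59 CPM) and PDGFRB (0.162 to 0.569 CPM) rose, but stromal cells would bring COL1A2, COL3A1, DCN and LUM with them, so these values argue against such cells as the source of VIM and leave a rise of some stromal genes within the tumour cells untested. A full loss of the epithelial state by the whole population would have lowered EPCAM, CDH1, KRT8, KRT18 and KRT19 at least 2-fold. Their median log2 fold change was -0.17, with 3 lower and 2 higher past the threshold and none beyond 1.22-fold, which argues against a full loss. The wider epithelial list was lower (13 of 24 members, median -0.16, camera adjusted p = 0.015, adjusted p = 0.48 with an estimated correlation), with RAB25 at -1.12, ST14 at -1.02 and ESRP1 at -0.93 on the log2 scale. Against these, 5 members rose, EHF (5.40), GRHL2 (0.63), CDH1 (0.23), SPINT1 (0.21) and KRT19 (0.19), so the list went both ways and a partial loss stays open. A rise of VIM in a subpopulation may also remain and was not tested.

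The fall of cholesterol synthesis genes could follow from an excess of sterols, which would raise the LXR targets ABCA1, ABCG1, MYLIP, LPCAT3 and SMPDL3A. Only 1 of these 5 rose, ABCA1 (3.98-fold, edgeR adjusted p = 5.6e-07), while ABCG1 fell 2.62-fold and LPCAT3 1.26-fold. These values argue against a joint rise of the 5 targets. They do not settle whether sterols were in excess, because ABCA1 rose and ABCG1 was low in both groups (1.97 and 0.742 CPM). The family had a camera adjusted p of 0.79, adjusted p = 0.85 with an estimated correlation. Whether the fall reflects lower SREBP activity by another route was not tested.

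At 3 counts or fewer over one group and 5 CPM or more in the other stood 8 rows, 6 higher and 2 lower in resistant libraries, 5 of them without a gene name. CSRNP3 had 0 counts over the parental and 659 over the resistant libraries, and no fold is given. HYDIN had 1 and 728 counts, a ratio of 700 with a 95% counting interval of 125 to 27690, and is uncertain because HYDIN2 is a close copy.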
